A study of Mus musculus with 12 samples.

How the data were processed

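RNA was measured on 12 Affymetrix whole-transcriptome arrays, 3 for each of 4 tissue pieces of the mouse hippocampus: the pyramidal cell layer of CA1, the stratum radiatum of CA1, and the same layers of CA2. The pyramidal layer holds the cell bodies of the excitatory neurons and is called the cell body layer here, and the stratum radiatum, into which their apical dendrites reach, is called the dendritic layer. Per the labels' protocols, the tissue came from 3 male Amigo2-EGFP mice on a C57BL/6J background, from separate litters and 6 to 8 weeks of age. Sections of 8 µm were used, and each of the 4 pieces was collected by laser capture microdissection from about 20 caps, with 5 sections on a cap. The extracts held 5 to 30 ng of RNA with an RNA integrity number of 6.9 to 7.5, and 5 to 7 ng was amplified with the Nugen WT-Ovation Pico kit. The protocols describe the arrays as a pilot for a sequencing study. They do not say whether the reporter, which is driven by the Amigo2 gene and marks CA2, guided the capture.

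The deposited values are log2 expression values made by the authors with RMA (robust multi-array average, which subtracts background, normalizes quantiles across arrays and summarizes the probes of a feature), per the submitters' processing notes. The software, its version and whether the arrays of both runs went into 1 normalization are not given in the sources used here. Quantile normalization within a set of arrays gives each array the same distribution of probe intensities, so a weaker labelled target can reach the values as raised dim features and a compressed range instead of as a lower median. The median over all features lay between 5.68 and 5.88 on the 12 arrays. The labels give all 6 CA1 arrays one run number and all 6 CA2 arrays the other, so region and run cannot be told apart in a comparison of CA2 with CA1, while each comparison of layers lay within a run. The difference between the layer differences of the regions is free of any run shift that was equal in both layers. An array gives no read depth, and the number of arrays limits the precision.

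The table held 72688 features. Of these, 32750 were in the platform annotation used here, 30604 with 1 gene symbol and 2146 with several, and the other 39938 were unnamed here and not used for named genes. Through Entrez identifiers, 22818 of the features with 1 symbol were matched to a RefSeq gene table, which changed 827 symbols. For each of 355 genes with more than 1 such feature, the feature with the highest mean over all arrays was kept, which left 30142 genes. The other features of these genes were called in the opposite direction in 5 genes for the layers of CA1, 1 gene for the layers of CA2 and 2 genes for the cell body layers.

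Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit of all 12 arrays with 4 group means and the replicate number as a fixed block, and p-values were adjusted by the Benjamini-Hochberg method over the 30142 genes. A gene was called at an adjusted p under 0.05. All tests were two-sided. The comparisons were the dendritic against the cell body layer in CA1 and in CA2, the difference between these differences (CA2 minus CA1, called the interaction), and CA2 against CA1 within each layer. A total of 29 gene lists, covering neuron and glia markers, RNAs known from dendrites or cell bodies, mitochondrial, metabolic and ribosomal genes, receptors, channels and matrix, were tested with camera at a preset correlation of 0.01 and adjusted over the lists. For each list the members called over all genes and those called when p-values were adjusted over the list alone were counted. Camera with a correlation estimated for each list and fry were run beside it. The list medians, means and test directions differed in sign in 23 of the 145 list tests, and 0 of these 23 passed the preset-correlation camera test. The comparisons, tests, gene lists and named-gene rule were fixed before the data were examined.

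The rule for named genes took, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among those called with the same sign in all 3 same-numbered pairs, and up to 4 members of each list with the smallest p. Amigo2, Rgs14, Pcp4, Wfs1, Fibcd1, Pou3f1, Camk2a, Map2, Ddn, Neurod6, Gfap and Mbp are given in each comparison whatever their value. Predicted genes, small RNAs and olfactory, vomeronasal and taste receptors were counted but not named. The genes in the text are a part of those the rule took, and members that went against their list are named where stated.

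The protocols tie 4 captured pieces to each mouse and number the arrays of a group 1 to 3, but no label says in words that the number stands for the mouse. Of the 18 pairs of arrays with the same number in different groups, 1 had deviations from the group means that correlated above 0.1 (range -0.346 to 0.132), and the highest correlation of a pair with other numbers was 0.251. The array most like another in a different group carried the same number for 4 of the 12 arrays. The pairing thus came from the protocols and not from the data, and the block was kept because pieces of 1 mouse are not independent. Where the fit without the block changed a call, that value is given.

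The same steps were tested on simulated values with 200 of 30142 genes changed. Of genes changed by 1 on the log2 scale, 93% were recovered for the layers of CA1, 92% for the layers of CA2, 79% for the interaction, 95% for the cell body layers and 91% for the dendritic layers, with between 6 and 11 false calls. At a change of 0.5 these shares were 66%, 56%, 26%, 56% and 58%. Each gene was simulated with 1 spread for all groups. The real groups differed in spread, so these shares and false calls do not cover that case. The alternatives were fits without the block, with the block as a random effect, on the compared groups alone, after quantile normalization or median centring of the deposited values, on genes above the median level, on every feature, with an intensity trend, with a 2-fold minimum, and without each replicate number or each array. A fit without 3 CA2 arrays with high oocyte transcripts and a fit with array weights were added after the data were seen. The first keeps 1 CA2 dendrite array, so wherever it is given, lower counts and lost calls can also come from fewer arrays. No sample was left out of the main results.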

Results

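Gene expression was measured in 4 laser-captured pieces of the mouse hippocampus, the cell body and dendritic layers of CA1 and of CA2, with 3 arrays for each. CA1 and CA2 are neighbouring fields of pyramidal neurons, and the dendritic layer also holds axons, interneurons, glia and blood vessels. Values are log2 expression as normalized by the authors, group values are means ± SD of 3 arrays, and a difference of 1 is a 2-fold difference. The 10 largest rises and falls of each comparison leave aside predicted genes and small RNAs. The first principal component of the 30142 genes took 58.3% of the variance and separated the layers, and the second took 19.9% and separated the regions. Within groups, gene values of array pairs correlated at 0.990 to 0.991 in the CA1 dendritic layer, 0.997 in the CA1 cell body layer, 0.995 to 0.997 in the CA2 cell body layer and 0.993 to 0.995 in the CA2 dendritic layer. The median SD of a gene within a group was 0.129 in the CA1 dendritic layer and 0.0751, 0.0721 and 0.0929 in the other groups in that order. Hybridization controls, which are added in equal amounts before hybridization, read 13.07 ± 0.04 on the CA1 dendrite arrays and 12.47 ± 0.03, 12.12 ± 0.04 and 12.53 ± 0.14 on the others. Features for external control RNAs without mouse sequence read 5.34 ± 0.07, 5.23 ± 0.01, 5.28 ± 0.02 and 5.26 ± 0.03. Poly-A controls read 8.07 ± 0.49 on the CA1 dendrite and 10.89 ± 0.20 on the CA1 cell body arrays, and 8.66 ± 0.11 on the CA2 cell body and 9.53 ± 0.14 on the CA2 dendrite arrays, so they were lower in the dendritic layer in CA1 and higher in it in CA2.

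**Figure D1:**
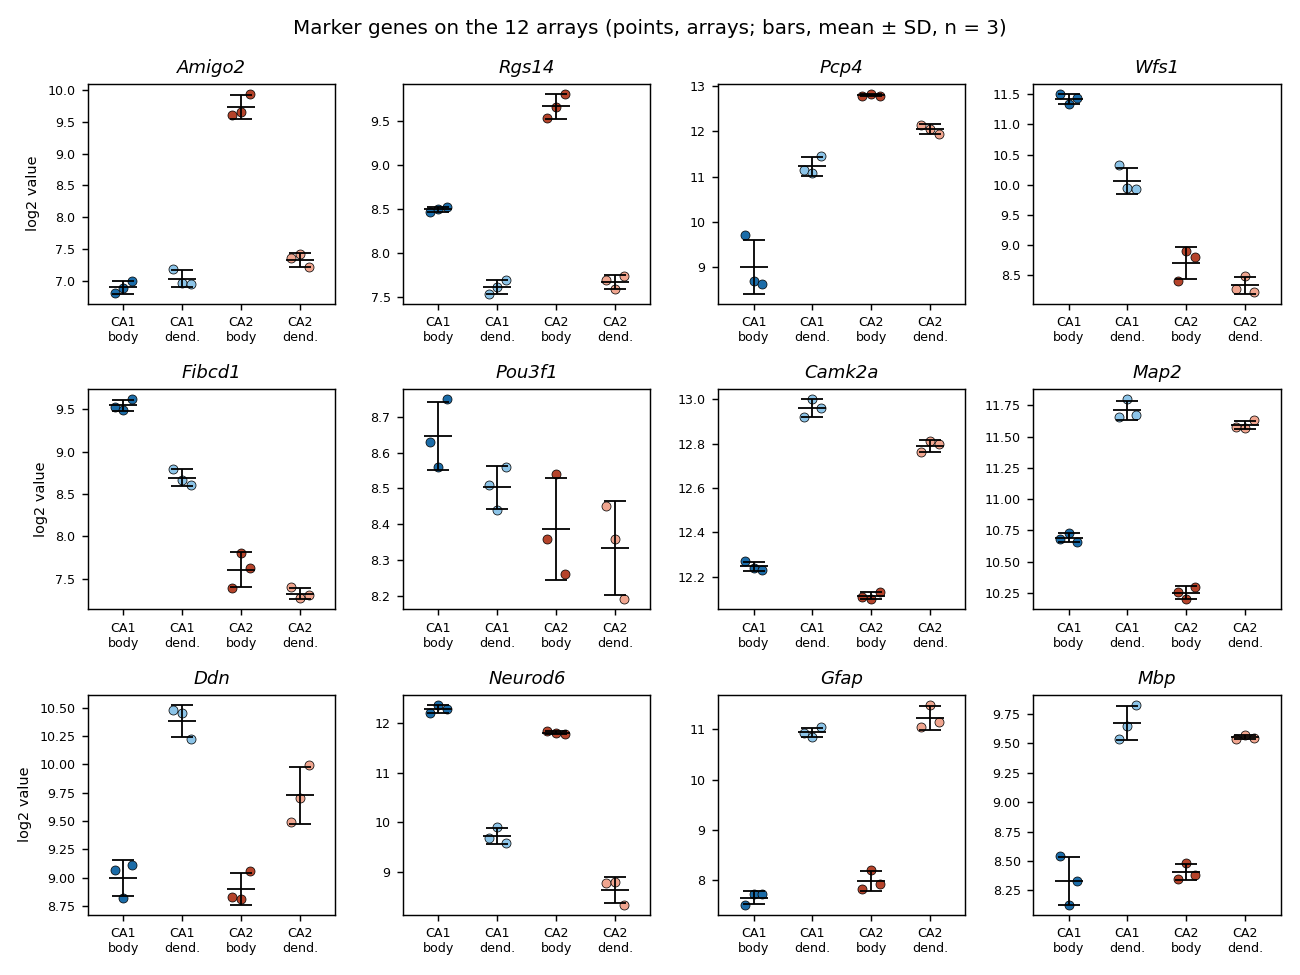
Log2 expression of 12 genes on each array of the 4 groups, with bars for the mean ± SD of 3 arrays. Neurod6 was highest in the cell body layers and Gfap in the dendritic layers of both regions, while Amigo2 stood at 9.73 ± 0.18 in the CA2 cell body layer and between 6.90 and 7.34 in the other groups.

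The first comparison asked which RNAs differ between the dendritic and cell body layers of CA1. All 19 astrocyte, 19 microglia and 17 endothelial markers were higher in the dendritic layer, as were 15 of 20 interneuron markers and 19 of 27 mRNAs known from dendrites, and 10 of 13 markers of CA1 neurons were lower. The last 3 lists lost their calls with an estimated correlation (adjusted p = 0.269, 0.171 and 0.163), and the first 3 kept them. Gfap, the intermediate filament of astrocytes, rose by 3.28 (SE 0.10, adjusted p = 1.5e-08), from 7.65 ± 0.12 to 10.94 ± 0.10. Neurod6, a transcription factor of pyramidal neurons, fell by 2.57 (SE 0.10, adjusted p = 4.3e-08), from 12.30 ± 0.08 to 9.73 ± 0.16. Camk2a, the calcium/calmodulin-dependent kinase whose mRNA is carried into dendrites, rose by 0.71, Map2, a microtubule protein of dendrites, by 1.02 and Ddn (dendrin) by 1.38.

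The 10 largest rises in CA1 ranged from 3.56 for Slc7a11, the cystine-glutamate exchanger, to 3.13 for Aldh1a1, a retinaldehyde dehydrogenase. They included Mgp (3.53), Ndnf (3.49), a secreted factor known from neurogliaform interneurons, and Igfbp5 (3.44). The 10 largest falls ranged from -3.35 for Rasd1, a Ras-related protein, to -2.55 for the ephrin receptor Epha4. Among them were the receptor Gpr22 (-3.13), Epha7 (-2.90), Spink8 (-2.66), the kinase Plk2 (-2.61) and Ndst4 (-2.57), an enzyme of heparan sulfate synthesis. Of the CA1 neuron genes given throughout, Wfs1 fell by 1.36 (adjusted p = 3.9e-05) and Fibcd1 by 0.85, while Pou3f1 differed by -0.14 (adjusted p = 0.24). Of the CA2 genes, Rgs14 fell by 0.88, Amigo2 differed by 0.13 (adjusted p = 0.34), and Pcp4, a calmodulin regulator, rose by 2.21 (SE 0.21, adjusted p = 1.7e-05), from 9.01 ± 0.60 to 11.22 ± 0.21. The myelin gene Mbp rose by 1.34.

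All 19 astrocyte markers rose over all genes and adjusted over the list alone, with a median of 1.86 (camera adjusted p = 4.41e-15; adjusted p = 0.0193 with an estimated correlation). They included Mlc1 (2.63) and the glutamate transporter Slc1a3 (2.41). All 19 microglia markers rose by both counts, with a median of 2.55 (camera adjusted p = 4.41e-15; adjusted p = 0.014 with an estimated correlation), among them P2ry13 (3.23), Tyrobp (3.14), Cx3cr1 (2.70) and Csf1r (2.63). All 17 endothelial markers rose by both counts (median 2.05, camera adjusted p = 2.66e-11; adjusted p = 0.0207 with an estimated correlation), with Slco1c1, a thyroid hormone transporter of brain vessels, at 2.95. Of 11 oligodendrocyte precursor markers, 10 rose and 1 fell by both counts (median 1.01, camera adjusted p = 1.47e-05; adjusted p = 0.0216 with an estimated correlation). Of 16 oligodendrocyte markers, 15 rose over all genes and 16 adjusted over the list alone, among them Mobp (2.30), and all 12 mural cell markers rose by both counts, among them Rgs5 (2.40). Their medians were 1.46 (camera adjusted p = 5.53e-09) and 1.28 (4.06e-07), with adjusted p = 0.123 and adjusted p = 0.136 with an estimated correlation. Of 20 interneuron markers, 15 rose and 2 fell by both counts (median 0.73, camera adjusted p = 6.39e-04; adjusted p = 0.269 with an estimated correlation). Gad2, which makes GABA, rose by 1.65 and the neuropeptide Npy by 1.85, while Pvalb fell by 0.57 and Cck by 0.88; these members were named after their values were seen.

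Of 27 mRNAs fixed as dendritically localized, 19 rose, 5 fell and 3 did not pass, by both counts (median 0.92, camera adjusted p = 5.86e-05; adjusted p = 0.171 with an estimated correlation). The postsynaptic scaffold Shank1 rose by 1.81, Ppp1r9b (spinophilin) by 1.73, the elongation factor Eef2 by 1.45 and the motor Kif5a by 1.41. Of those that fell, Nrgn (neurogranin, -0.84) and Camkv (-0.51) were named after their values were seen. All 34 measured cytosolic ribosomal protein genes, of 79 fixed, rose by both counts (median 0.51, camera adjusted p = 1.77e-10; adjusted p = 0.0939 with an estimated correlation), with Rpsa at 1.31. Of 74 mitochondrial ribosomal protein genes, 47 fell and 1 rose over all genes, and 50 fell and 1 rose adjusted over the list alone (median -0.31, camera adjusted p = 1.69e-12; adjusted p = 0.0939 with an estimated correlation), with Mrps9 at -1.17 and Mrpl11 at -1.04. The external control features were 0.11 higher on the CA1 dendrite than on the CA1 cell body arrays, and the hybridization controls 0.60 higher.

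Of 18 transcripts fixed as somatic, 14 fell and 3 rose by both counts (median -0.58, camera adjusted p = 2.67e-05; adjusted p = 0.0939 with an estimated correlation). Of 13 CA1 neuron markers, 10 fell and 2 rose by both counts (median -1.17, camera adjusted p = 2.54e-06; adjusted p = 0.163 with an estimated correlation), with Man1a, a Golgi mannosidase, at -2.48. The 2 that rose, Dcn (1.35), which encodes the matrix protein decorin of fibroblasts, and Mpped1 (0.33), were named after their values were seen. Of 18 CA2 markers, 8 rose and 5 fell (median 0.12, camera adjusted p = 0.909), among them the calcium-binding Necab2 (1.09) and the matrix gene Vcan (2.14), which is also a precursor marker. Among 14 ionotropic glutamate receptor genes, 7 rose and 6 fell (camera adjusted p = 0.231), and Grin2a, Grin2b and Gria2 fell by 1.91, 1.85 and 1.57. In the calcium list, the pump Atp2b1 (-1.94) and exchanger Slc8a1 (-1.93) fell and the sensor Ncs1 rose by 2.04. Of 15 glycolysis genes, 10 fell and 3 rose over all genes, and 10 fell and 4 rose adjusted over the list alone (median -0.38, camera adjusted p = 0.0025; adjusted p = 0.269 with an estimated correlation). Neuronal enolase Eno2 fell by 0.76, and Aldoc, the aldolase of astrocytes, rose by 1.86.

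In CA1, 14122 of 30142 genes were called, 8538 higher and 5584 lower in the dendritic layer, and 13940 of them had the same sign in all 3 numbered pairs. At least 2-fold, 998 were higher and 851 lower. A fit of these 2 groups alone called 11673 genes, 56.9% of them higher. The CA1 dendritic layer varied more than the other groups, which share the spread estimate of the main fit, so 14122 may be too high. Rises made up 60.5% of all called genes, 52.0% of those above the median level of features and 91.0% of those at or below it; the share was 56.5% after quantile normalization, 52.9% after median centring and 36.7% among the brightest 20% of genes. Of the 29 lists, 23 passed with the preset correlation and 4 with an estimated one. After quantile normalization the lists of complex I, potassium channel, calcium, mitochondrial dynamics and immediate early genes did not pass, and the complex I median changed from -0.12 to 0.02; without the replicate block the immediate early gene list did not pass (adjusted p = 0.0563).

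**Figure D2:**
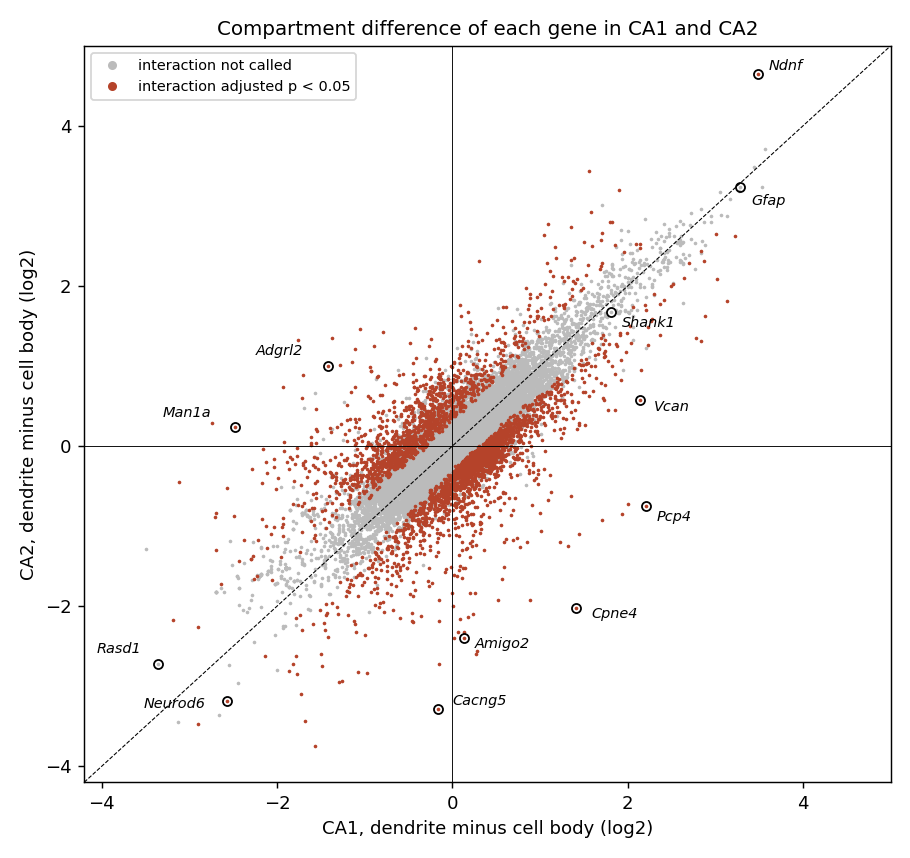
Log2 difference of each gene between the dendritic and cell body layer in CA1 (horizontal) against that in CA2 (vertical), with the line of equal differences dashed, genes with an interaction adjusted p under 0.05 in red and named genes circled. Across the 30142 genes the Pearson correlation was 0.777, and Pcp4 lay at 2.21 in CA1 and -0.75 in CA2.

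The same layers were compared in CA2. All astrocyte, microglia and endothelial markers measured and 14 of 20 interneuron markers were higher in the dendritic layer, and 16 of 18 markers of CA2 neurons were lower. Of these lists, the interneuron list lost its call with an estimated correlation (adjusted p = 0.144). Gfap rose by 3.24 (SE 0.10, adjusted p = 1.6e-08), from 7.98 ± 0.19 to 11.23 ± 0.23, and Neurod6 fell by 3.18 (SE 0.10, adjusted p = 1.4e-08), from 11.81 ± 0.03 to 8.63 ± 0.26. Ndnf rose by 4.65 (SE 0.13, adjusted p = 1.0e-08) and Slc9a4, a sodium-proton exchanger, fell by 3.75. Amigo2, an adhesion gene that marks CA2 and drives the reporter of these mice, fell by 2.39 (SE 0.11, adjusted p = 1.1e-07), from 9.73 ± 0.18 to 7.34 ± 0.11.

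The 10 largest rises in CA2 lay between 4.65 for Ndnf and 2.97 for Ifitm3, an interferon-induced membrane protein. Among them were Slc7a11 (3.71), Igfbp5 (3.49), the smooth muscle actin Acta2 (3.20) and the organic anion transporter Slco1a4 (3.18). The 10 largest falls, from -3.75 for Slc9a4 to -2.94 for the channel subunit Kcnv1, included Gpr22 (-3.45), the prostaglandin synthase Ptgs2 (-3.44), Spink8 (-3.36), Cacng5 (-3.28), an auxiliary subunit of AMPA receptors, and the potassium channel Kcna4 (-2.96). Rgs14, a signalling scaffold of CA2 neurons, fell by 1.99, and Pcp4 differed by -0.75 (SE 0.21, adjusted p = 0.019), from 12.80 ± 0.03 to 12.04 ± 0.11. The CA1 genes Wfs1 (-0.37, adjusted p = 0.084), Fibcd1 (-0.28, adjusted p = 0.062) and Pou3f1 (-0.05, adjusted p = 0.74) did not pass. Fibcd1 passed in 8 alternatives, among them without the replicate block (adjusted p = 0.0359), after quantile normalization (0.041) or median centring (0.0335), and without replicate 1 (-0.43, adjusted p = 0.0154) or CA2 cell body 1 (-0.42, adjusted p = 0.0063). Wfs1 passed without the 3 arrays with oocyte transcripts (-0.82, adjusted p = 0.0115), without replicate 1 (0.0117) or CA2 cell body 1 (0.00629), on the 2 groups alone (0.0385) and with array weights (0.038). Camk2a rose by 0.68, Map2 by 1.34, Ddn by 0.83 (adjusted p = 4.8e-04) and Mbp by 1.15.

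All 19 astrocyte markers (median 1.62), 19 microglia markers (2.10), 17 endothelial markers (1.70) and 11 oligodendrocyte precursor markers (0.81) rose over all genes and adjusted over the list alone. Their camera adjusted p-values were 7.49e-21, 1.69e-18, 4.28e-17 and 3.12e-09, and each had an adjusted p = 0.00494 with an estimated correlation. Examples are the glutamate transporter Slc1a2 (2.08), the growth factor receptor Csf1r (2.29) and the efflux pump Abcb1a (2.47). Of 16 oligodendrocyte markers, 15 rose by both counts, with Ermn (ermin) at 2.49, and all 12 mural markers rose by both counts. Their medians were 1.67 (camera adjusted p = 4.12e-13) and 1.59 (8.05e-11), and both had an adjusted p = 0.0619 with an estimated correlation. Of 20 interneuron markers, 14 rose and 1 fell over all genes, and 16 rose and 1 fell adjusted over the list alone (median 0.75, camera adjusted p = 2.66e-07; adjusted p = 0.144 with an estimated correlation). Reln rose by 2.66 and Gad1 by 1.57, and the 1 that fell was Cck (-1.41), a neuropeptide also made by pyramidal neurons.

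Of 18 CA2 markers, 16 fell and 2 rose by both counts (median -1.22, camera adjusted p = 7.24e-11; adjusted p = 0.027 with an estimated correlation), among them Sostdc1 (-2.56) and the kinase Map3k15 (-2.40). Of 13 CA1 markers, 3 fell and 1 rose over all genes, and 4 fell and 3 rose adjusted over the list alone (median -0.19, camera adjusted p = 0.321). The members ranged from -3.36 for Spink8 to 2.26 for Dcn. Without replicate 1 the list passed (-0.36, camera adjusted p = 0.0321). Of 18 somatic transcripts, 15 fell and 3 rose by both counts (median -1.20, camera adjusted p = 8.02e-08; adjusted p = 0.0426 with an estimated correlation), with the thyroid hormone-binding Crym at -2.24 and Uchl1 at -1.45. Of 27 dendritic mRNAs, 18 rose and 6 fell by both counts (median 0.46, camera adjusted p = 1.26e-04; adjusted p = 0.194 with an estimated correlation). Shank1 rose by 1.67, and of those that fell, Nrgn (-1.44) and Camkv (-1.18) were named after their values were seen, as was Cck. Of 34 cytosolic ribosomal protein genes, 33 rose by both counts (median 0.54, camera adjusted p = 6.76e-17; adjusted p = 0.0426 with an estimated correlation), with Rpsa at 1.10. Of 74 mitochondrial ribosomal protein genes, 45 fell and 3 rose over all genes, and 47 fell and 4 rose adjusted over the list alone (median -0.35, camera adjusted p = 1.18e-07; adjusted p = 0.144 with an estimated correlation), with Mrpl19 at -0.81. Of 18 enzymes of the TCA cycle, 14 fell and 2 rose by both counts (median -0.40, camera adjusted p = 0.00121; adjusted p = 0.194 with an estimated correlation), with Idh3a at -1.14.

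Of 17 matrix and perineuronal net genes, 11 rose and 3 fell (median 0.43, camera adjusted p = 0.00238; adjusted p = 0.0487 with an estimated correlation). The link protein Hapln1 rose by 2.25, and Acan (aggrecan), the core proteoglycan of perineuronal nets, fell by 1.53. The CA3 marker Cpne4 fell by 2.02, the receptor gene Grin2a by 2.09, and Grm3 (2.80), Necab1 (2.63) and Grik1 (1.69) rose. In CA2, 10251 genes were called, 4888 higher and 5363 lower, of which 987 and 777 were at least 2-fold, and 10220 had the same sign in all 3 pairs. Rises made up 47.7% of the called genes, 55.3% over every feature and 53.4% without the arrays with oocyte transcripts. Of the 29 lists, 19 passed with the preset correlation and 8 with an estimated one. Oocyte transcripts were high on 1 of the 3 CA2 cell body and 2 of the 3 CA2 dendrite arrays; without these, 5707 genes were called, and Pcp4 (adjusted p = 0.12) and Ddn (adjusted p = 0.209) did not pass. The Pcp4 call was also lost without replicate 2 (adjusted p = 0.109), replicate 3 (0.0772), CA2 cell body 2 (0.087) or 3 (0.069), or CA2 dendrite 1 (0.0692) or 3 (0.0647).

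The layer differences of CA1 and CA2 overlapped. Of the 30142 genes, 3748 were higher and 3680 were lower in the dendritic layer of both regions, where independent lists of these sizes would share 1384.6 and 993.5, and 352 were called in opposite directions. Across genes, which are not independent replicates, the differences correlated at r = 0.777 (Pearson) and rho = 0.637 (Spearman). No array served in both comparisons. Without the 3 arrays with oocyte transcripts, fewer genes than the 7428 of the main fit were called in the same direction. As that fit keeps 1 CA2 dendrite array, the fall cannot be assigned to these transcripts.

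The interaction tested whether the layer difference itself differed between CA2 and CA1, and a negative value means a lower dendrite-to-cell-body difference in CA2. Of 18 markers of CA2 neurons 17 were lower, and of 13 markers of CA1 neurons 7 were higher. The CA2 markers averaged 8.84 in the CA2 cell body layer and 7.13 to 7.49 in the other groups. The CA1 markers averaged 9.07 in the CA1 cell body layer and 7.21 to 7.92 in the other groups. A marker that is low in the cell bodies of 1 region has little room to fall there. These 2 results therefore largely restate the regional levels and do not show a difference in RNA localization. The same limit holds for single genes below whose cell body levels differed between the regions, such as Cpne4 (6.27 in CA1 and 11.27 in CA2 cell bodies). The CA1 list lost its call with an estimated correlation (adjusted p = 0.234), and the CA2 list kept it (adjusted p = 0.0205). Cpne4, a copine of CA2 and CA3 neurons, gave -3.43 (SE 0.23, adjusted p = 2.9e-05), Cacng5 -3.12 (SE 0.14, adjusted p = 4.2e-06) and Pcp4 -2.97 (SE 0.30, adjusted p = 3.2e-04). Man1a gave 2.71 (SE 0.12, adjusted p = 4.2e-06), C1ql3 2.59 (SE 0.31, adjusted p = 8.1e-04) and Calb1 (calbindin) 2.51 (SE 0.32, adjusted p = 0.0013).

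The 10 largest positive values ended at 2.05 for Ndst4 and included the latrophilin Adgrl2 (2.42), and the 10 largest negative values ended at -2.56 for St8sia6, a sialyltransferase, and included Sostdc1 (-2.84), Mctp1 (-2.81), Fstl5 (-2.79) and Nrip3 (-2.63). Amigo2 gave -2.53 (adjusted p = 1.8e-05), Rgs14 -1.11, Wfs1 0.99 (adjusted p = 0.016), Fibcd1 0.57 (adjusted p = 0.036) and Neurod6 -0.61 (adjusted p = 0.022). The interaction was not called for Pou3f1 (0.09, adjusted p = 0.67), Camk2a (-0.04, adjusted p = 0.78), Map2 (0.32, adjusted p = 0.053), Ddn (-0.56, adjusted p = 0.074), Gfap (-0.04, adjusted p = 0.87) or Mbp (-0.19, adjusted p = 0.40), although some passed under alternatives. Map2 did without the replicate block (adjusted p = 0.0277) and in 6 others, and Ddn did after quantile normalization (-0.70, adjusted p = 0.035), with array weights (0.0467) and without CA1 dendrite 3 (0.0117) or CA2 dendrite 3 (0.0495).

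Of 18 CA2 markers, 17 were lower over all genes and 18 adjusted over the list alone (median -1.32, camera adjusted p = 3.49e-21; adjusted p = 0.0205 with an estimated correlation), with Map3k15 at -2.42 and Necab2 at -1.76. Of 13 CA1 markers, 7 were higher, with 9 higher and 1 lower adjusted over the list alone (median 0.91, camera adjusted p = 2.28e-07; adjusted p = 0.234 with an estimated correlation), among them the potassium channel Kcnh7 (1.93) and the matricellular Ccn3 (1.75). Of 11 CA3 markers, 7 were lower and 1 higher, with 8 and 1 adjusted over the list alone. Their median was -0.47 (camera adjusted p = 7.02e-05, and adjusted p = 0.0541 with an estimated correlation). They averaged 6.93 in CA1 and 8.19 in CA2 cell bodies, so this list too partly restates the regional levels. Of 18 somatic transcripts, 11 were lower, with 16 adjusted over the list alone (median -0.51, camera adjusted p = 2.5e-06; adjusted p = 0.0772 with an estimated correlation), including Rprml (-1.29), the vesicular glutamate transporter Slc17a7 (-0.84) and Stmn2 (-0.71). Of 27 dendritic mRNAs, 14 were lower, with 18 lower and 2 higher adjusted over the list alone (median -0.37, camera adjusted p = 3.62e-04; adjusted p = 0.395 with an estimated correlation), with Psd at -0.92, Agap2 at -0.88, Dlgap3 at -0.71 and Cplx2 at -0.66.

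Of 19 microglia markers, 11 were lower, with 14 adjusted over the list alone (median -0.46, camera adjusted p = 5.11e-05; adjusted p = 0.0772 with an estimated correlation), with C1qa, a complement subunit, at -0.82, Itgam at -0.68, Fcrls at -0.54 and Trem2 at -0.41. The astrocyte list (median -0.05, camera adjusted p = 0.821) did not pass, nor did the oligodendrocyte list (median -0.06, camera adjusted p = 0.402). Of 20 interneuron markers, 3 were higher and 2 lower, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.0315; adjusted p = 0.717 with an estimated correlation), among them Reln (0.95) and Sst (-1.33). Of 7 nuclear-retained RNAs, 3 were higher by both counts (median 0.31, camera adjusted p = 8.75e-04; adjusted p = 0.0772 with an estimated correlation), among them Malat1 (0.44) and Kcnq1ot1 (0.74). Of 33 complex I genes, 2 were higher, Ndufv2 (0.44) and Ndufa7 (0.35), and 1 adjusted over the list alone (camera adjusted p = 2.1e-04; adjusted p = 0.299 with an estimated correlation). Of 74 mitochondrial ribosomal protein genes, 3 were higher (camera adjusted p = 0.00905; adjusted p = 0.711 with an estimated correlation). After quantile normalization neither list passed, and their medians changed from 0.13 to -0.02 and from 0.01 to -0.06. Over all genes the interaction had a median of -0.11 as deposited, and 11.6% of genes were called. These 2 lists thus stood out from a lower background more than by calls of their members. Acan (-1.67), Vcan (-1.56), the link protein Hapln4 (-1.48) and the mitochondrial calcium uniporter Mcu (-0.99) were also lower.

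The interaction was called for 3504 genes, 1450 higher and 2054 lower, all with 1 sign in all 3 numbered sets, and 414 had a difference of at least 2-fold. The higher share was 41.4% as deposited, 30.2% after quantile normalization, 61.5% over every feature and 53.1% with a 2-fold minimum, and it was 45.8% above the median level and 20.2% at or below it. Without the 3 arrays with oocyte transcripts 699 genes were called, and among the genes named, Wfs1, Fibcd1, Neurod6, C1ql3, Ccn3, Cplx2, Fcrls, Trem2, Stmn2, Ndufv2, Ndufa7, Malat1, Kcnq1ot1, Sst and Reln did not pass, nor did the interneuron and mitochondrial ribosomal lists. Of these, Fibcd1, Neurod6, Fcrls, Trem2, Ndufv2, Ndufa7 and Malat1 also lost their calls without any 1 replicate number, and Fibcd1 (adjusted p = 0.129), Ndufa7, Malat1 and the interneuron list after quantile normalization; Wfs1 lost its call without replicate 2 or 3. Kcnq1ot1 (adjusted p = 0.0717 and 0.0961) and Reln (0.105 and 0.0834) lost theirs without replicate 1 or 2. Cplx2 did so without replicate 2 or 3 (0.0551 and 0.0687), Ccn3 without replicate 2 (0.0509) and Sst without replicate 3 (0.0874). Of the other genes named, Itgam (adjusted p = 0.0545 and 0.0639) and Slc17a7 (0.0512 in both) lost theirs without replicate 1 or 3, C1qa without replicate 2 (0.075) and Dlgap3 without replicate 3 (0.083). Leaving out replicate 2 gave 697 called genes, so a fall like that without the 3 arrays can come from fewer arrays alone.

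CA2 was next compared with CA1 in the cell body layer, where region and run cannot be told apart. All 18 markers of CA2 neurons and 10 of 11 markers of CA3 neurons were higher in CA2, and 9 of 13 markers of CA1 neurons were lower. The CA1 list lost its call with an estimated correlation (adjusted p = 0.156). Cpne4 was higher by 5.01 (SE 0.16, adjusted p = 5.2e-08), at 11.27 ± 0.05 against 6.27 ± 0.12, and Pcp4 by 3.79 (SE 0.21, adjusted p = 1.5e-06), at 12.80 ± 0.03 against 9.01 ± 0.60. Wfs1, an endoplasmic reticulum protein, differed by -2.72 (SE 0.15, adjusted p = 1.2e-06) and Fibcd1 by -1.94. Amigo2 was higher by 2.83 (SE 0.11, adjusted p = 1.8e-07), and as the labels do not say whether its reporter guided the capture, it is not an independent mark of the region.

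The 10 largest rises ended at 3.08 for Map3k15 and included Mctp1 (3.99), a calcium-binding membrane protein, Nrip3 (3.82), Fstl5 (3.29), the synaptic adhesion gene Lrrtm4 (3.27), Cacng5 (3.21) and Kctd4 (3.11). The 10 largest falls ranged from -3.29 for Adgrl2 to -2.42 for Cd34, with C1ql3 (-3.21), Man1a (-2.96), Ndst4 (-2.92), Kcnh7 (-2.65), Calb1 (-2.59) and Ccn3 (-2.57) among them. Rgs14 was higher by 1.17. Neurod6 (-0.48, adjusted p = 0.0064) and Map2 (-0.44, adjusted p = 0.0011) were lower. Pou3f1 (-0.26, adjusted p = 0.089), Camk2a (-0.13, adjusted p = 0.14), Ddn (-0.10, adjusted p = 0.66) and Mbp (0.07, adjusted p = 0.72) did not pass. Camk2a did with an intensity trend (adjusted p = 0.0389), and Pou3f1 did without CA2 cell body 2 (-0.36, adjusted p = 0.0429) and with array weights (0.0485). Gfap was higher by 0.33 (adjusted p = 0.047), and without the replicate block it did not pass (adjusted p = 0.0788), nor without any 1 cell body array.

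All 18 CA2 markers were higher by both counts (median 1.32, camera adjusted p = 5.26e-24; adjusted p = 0.00732 with an estimated correlation), among them Sostdc1 (3.03). Of 11 CA3 markers, 10 were higher by both counts (median 0.67, camera adjusted p = 5.49e-10; adjusted p = 0.00732 with an estimated correlation), with Il16 at 1.98, the kainate receptor Grik4 at 1.87 and Iyd at 1.74. Of 13 CA1 markers, 9 were lower over all genes and 10 adjusted over the list alone (median -1.94, camera adjusted p = 1.08e-11; adjusted p = 0.156 with an estimated correlation), among them Mpped1 (-1.32). Of 16 oligodendrocyte markers, 14 were higher, with 15 adjusted over the list alone (median 0.62, camera adjusted p = 1.06e-08; adjusted p = 0.21 with an estimated correlation), with Mobp at 1.18 and Ermn at 1.14. Of 17 endothelial markers, 7 were higher (median 0.29, camera adjusted p = 6.21e-04; adjusted p = 0.186 with an estimated correlation), with 9 higher and 1 lower adjusted over the list alone, while the microglia list did not pass (camera adjusted p = 0.435).

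Of 20 immediate early genes, which neuronal activity induces, 10 were lower in CA2 cell bodies, with 11 lower and 1 higher adjusted over the list alone (median -0.55, camera adjusted p = 3.65e-04; adjusted p = 0.34 with an estimated correlation). Dusp6 stood at -1.48, Arc at -1.14, Egr3 at -0.93 and Homer1 at -0.65. Of 22 mitochondrial dynamics and calcium uptake genes, 9 were higher and 2 lower, with 14 and 3 adjusted over the list alone (median 0.20, camera adjusted p = 0.00103; adjusted p = 0.215 with an estimated correlation), with Mcu at 0.98, its regulator Mcur1 at 0.86 and Ppargc1a, a coactivator of mitochondrial biogenesis, at 0.44. Of 18 TCA cycle enzymes, 9 were higher, with 11 adjusted over the list alone (median 0.24, camera adjusted p = 4.11e-04; adjusted p = 0.215 with an estimated correlation), with Sucla2 at 0.55. Of 34 cytosolic ribosomal protein genes, 16 were lower, with 17 adjusted over the list alone (median -0.18, camera adjusted p = 1.28e-05; adjusted p = 0.257 with an estimated correlation), with Rpl35 at -0.54 and Rpsa at -0.51. Of 7 nuclear-retained RNAs, 3 were lower, with 4 adjusted over the list alone (median -0.19, camera adjusted p = 0.00413; adjusted p = 0.156 with an estimated correlation), with Snhg11 at -1.12. Acan (1.65), Hapln4 (1.46), Vcan (1.44) and the kinase Camk4 (1.40) were higher, and Grm3 was lower (-1.55).

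Between the cell body layers 6367 genes were called, 3205 higher and 3162 lower in CA2, of which 267 and 358 were at least 2-fold. Of the 29 lists, 14 passed with the preset correlation and 2 with an estimated one. The higher share was 50.3% as deposited, 70.4% after quantile normalization, 74.3% after median centring and 33.3% over every feature. The Neurod6 call was lost without replicate 2 (adjusted p = 0.0779).

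**Figure D3:**
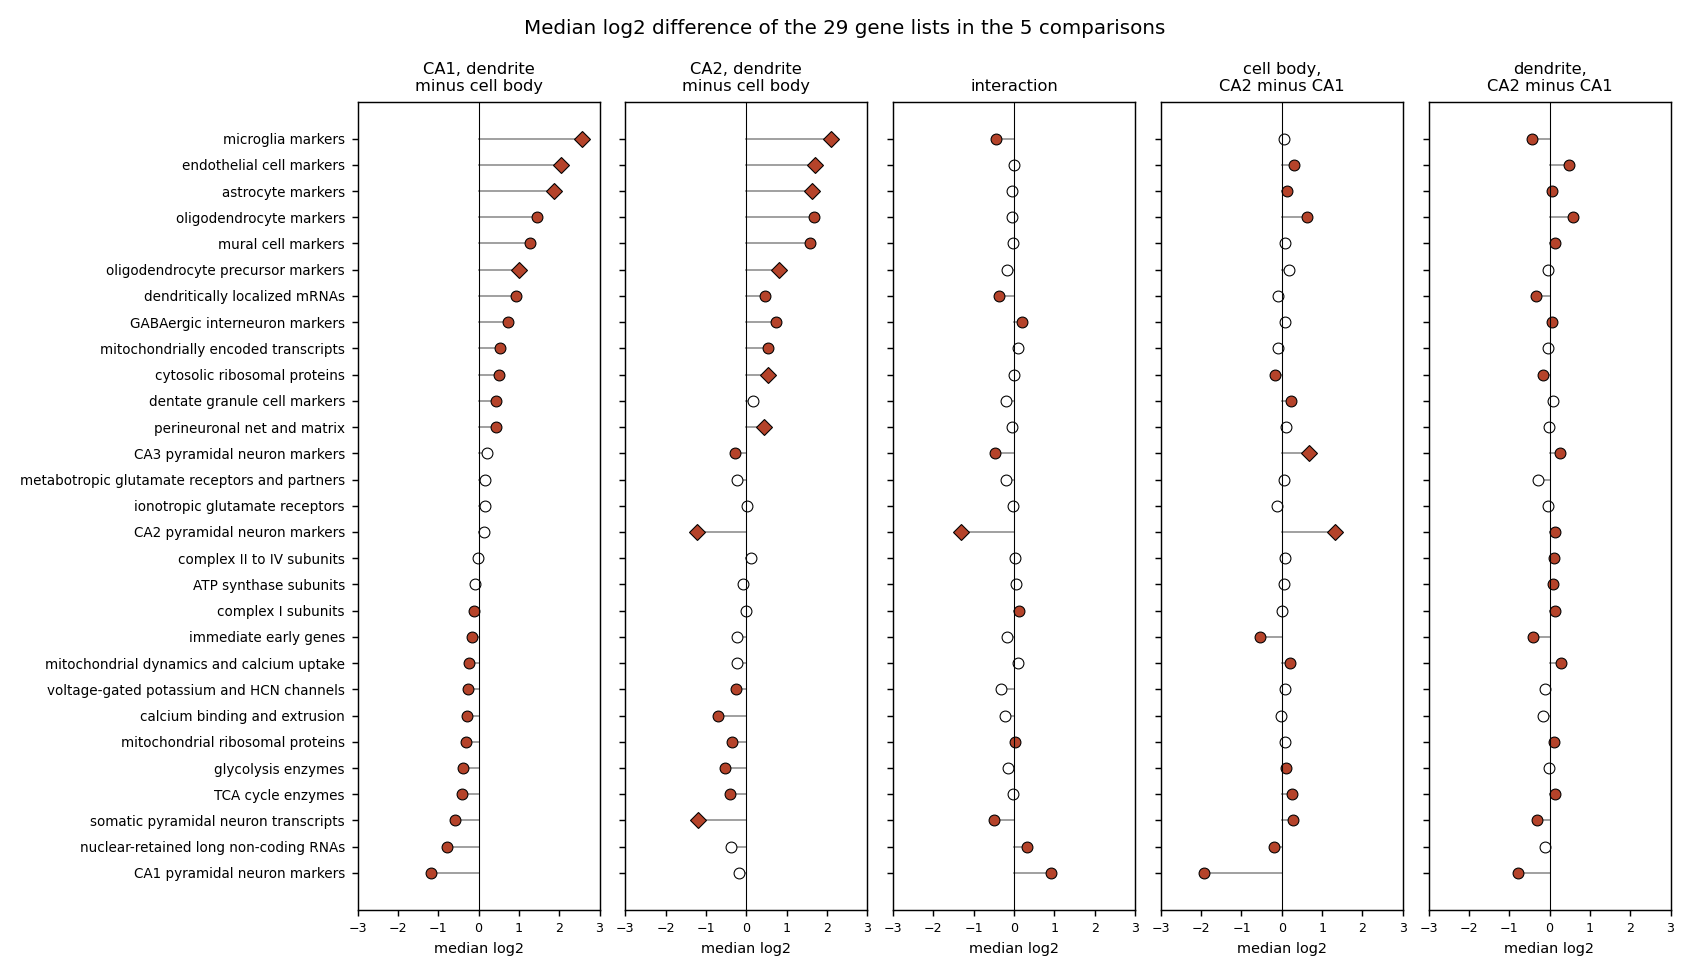
Median log2 difference of the gene lists in the comparisons, with filled symbols for a camera adjusted p under 0.05 at the preset correlation, diamonds for lists that also passed with an estimated correlation and open symbols for the rest. The CA2 marker list lay at 1.32 between the cell body layers and at 0.13 between the dendritic layers.

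The same comparison in the dendritic layer, where region and run again cannot be told apart, addressed the distinct dendritic transcriptome and the mitochondrial genes of CA2 named in the study's title. The pieces also held glia, vessels and interneurons. A different mix of cells can therefore not be told apart from a difference within dendrites, for mitochondrial genes and dendritic mRNAs too. The median over all genes was -0.11 as deposited, -0.02 after quantile normalization and -0.002 after median centring, so list medians are given relative to all genes here. It was 0.05 among the brightest 20% of genes and -0.19 among the dimmest 20%, so part of the relative median of a list of bright genes is this shift with level. At the preset correlation the dendritic mRNA list was lower in CA2, and the oligodendrocyte and endothelial lists and those of mitochondrial ribosomes, mitochondrial dynamics, the TCA cycle and the respiratory complexes were higher. With an estimated correlation no list of this comparison passed (lowest adjusted p = 0.0713), and the transcripts encoded in mitochondria did not pass by either. Itpka, a kinase of inositol trisphosphate that binds actin in spines, differed by -2.83 (SE 0.10, adjusted p = 1.5e-06), at 7.28 ± 0.07 in CA2 against 10.12 ± 0.12 in CA1. Ermn was higher by 1.76 (SE 0.17, adjusted p = 1.3e-04) and the ribosome biogenesis gene Brix1 by 1.78 (SE 0.10, adjusted p = 1.2e-05).

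The 10 largest falls began with Itpka and included Doc2b (-2.54), a calcium sensor of vesicle release, Wfs1 (-1.73), Rasgrp1 (-1.66), Phyhip (-1.64), Git1 (-1.54), the somatostatin receptor Sstr4 (-1.54) and beta-spectrin Sptb (-1.52). The 10 largest rises, from 3.14 to 1.57, included 5 genes known from oocytes, among them Elobl (3.14, SE 0.98, adjusted p = 0.037), Nlrp14 (2.86), Fbxw14 (2.67) and the egg coat gene Zp2 (1.67). The others included Cdh19 (1.96), Pdgfd (1.58) and Cpne4 (1.57). Elobl was at 9.42 on CA2 cell body 1, 9.59 on CA2 dendrite 2 and 9.32 on CA2 dendrite 3, and between 4.72 and 6.48 on the other 9 arrays. The calls of Elobl (adjusted p = 0.0889), Fbxw14 and Zp2 were lost without these 3 arrays, and those of all 4 were lost without CA2 dendrite 2 or CA2 dendrite 3, without replicate 2 or 3, without any 1 CA1 dendrite array, and with array weights.

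**Figure D4:**
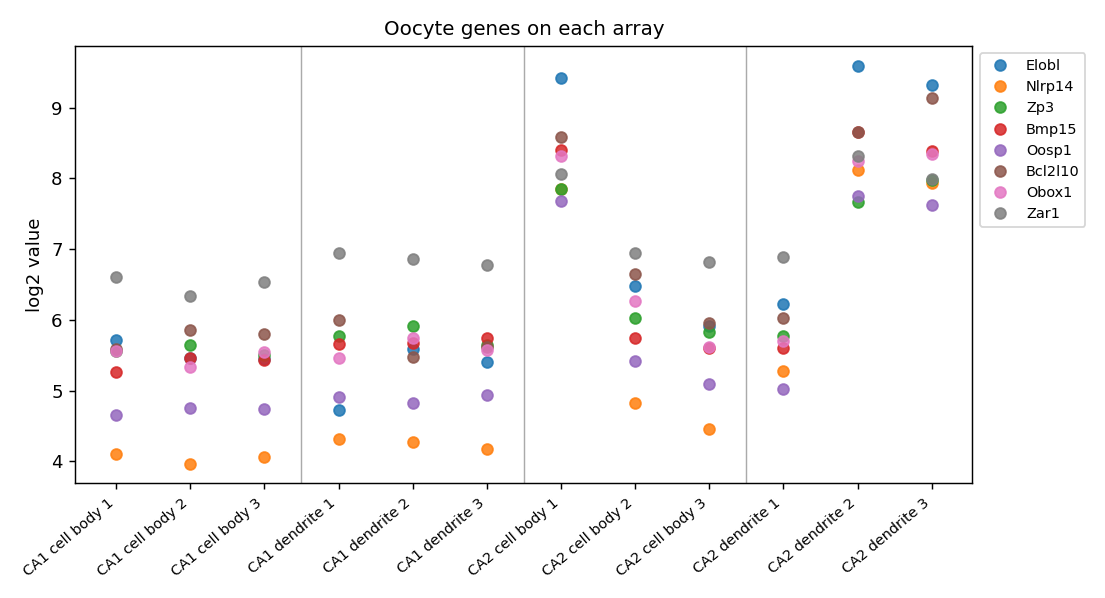
Log2 expression of 8 oocyte genes on each of the 12 arrays. CA2 cell body 1 and CA2 dendrite 2 and 3 stood apart, with Bmp15 at 8.40, 8.66 and 8.39 against 5.26 to 5.75 elsewhere.

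Of the genes given throughout, Fibcd1 (-1.37), Neurod6 (-1.10) and Ddn (-0.66, adjusted p = 0.0048) were lower, and Pcp4 was higher by 0.82 (adjusted p = 0.019). Camk2a differed by -0.17 (adjusted p = 0.049), a call lost in 14 alternatives, among them median centring (-0.06, adjusted p = 0.522), quantile normalization (0.213), the 2 groups alone (0.238) and without any 1 replicate number or dendrite array. Amigo2 (0.30, adjusted p = 0.065), Rgs14 (0.06, adjusted p = 0.54), Pou3f1 (-0.17, adjusted p = 0.19), Map2 (-0.12, adjusted p = 0.19), Gfap (0.29, adjusted p = 0.058) and Mbp (-0.12, adjusted p = 0.40) did not pass. Amigo2 did in several alternatives, among them without the replicate block (adjusted p = 0.0415) and with it as a random effect (0.0457). It also did after quantile normalization (0.0482), after median centring (0.0255) and without CA1 dendrite 1 (0.0314). Gfap did after median centring (0.0297), on genes above the median level (0.0462), with an intensity trend (0.0482) and without CA1 dendrite 3 (0.0456), among others. Of 18 CA2 markers, 5 were higher and 2 lower, with 7 and 2 adjusted over the list alone (median 0.24 relative to all genes, camera adjusted p = 0.0155; adjusted p = 0.303 with an estimated correlation). Necab2 stood at 0.74 and Map3k15 at 0.66, and the mineralocorticoid receptor Nr3c2 (-0.64) and vasopressin receptor Avpr1b (-0.26, adjusted p = 0.013) were lower. The Avpr1b call was lost on the 2 groups alone (adjusted p = 0.116), after quantile normalization (0.071) or median centring (0.103), and without any 1 replicate number or CA2 dendrite 2. Of 13 CA1 markers, 8 were lower and 1 higher, with 9 and 1 adjusted over the list alone (median -0.66, camera adjusted p = 2.6e-04; adjusted p = 0.303 with an estimated correlation), with Mpped1 at -1.46 and the serotonin receptor Htr1a at -1.28. Of 11 CA3 markers, 6 were higher, with 8 adjusted over the list alone (median 0.37, camera adjusted p = 1.01e-05; adjusted p = 0.0713 with an estimated correlation).

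Of 27 dendritic mRNAs, 17 were lower and 1 higher in CA2, with 19 and 1 adjusted over the list alone (median -0.24, camera adjusted p = 1.01e-05; adjusted p = 0.215 with an estimated correlation). Camkv and Psd both stood at -1.14, Sipa1l1 at -0.74 and the scaffold Dlgap1 at -0.73, and the calcium signalling kinases Camkk2 (-0.80) and Camk2b (-0.72) were also lower. Of 20 immediate early genes, 9 were lower, with 14 adjusted over the list alone (median -0.29, camera adjusted p = 6.76e-04; adjusted p = 0.303 with an estimated correlation), with Arc at -1.39, Egr3 at -1.27 and Homer1 at -0.82. Of 18 somatic transcripts, 10 were lower, with 10 lower and 2 higher adjusted over the list alone (median -0.21, camera adjusted p = 0.0353; adjusted p = 0.303 with an estimated correlation), with Rprml at -1.25; the list did not pass without replicate 1 (adjusted p = 0.0804) or 3 (0.173). Of 34 cytosolic ribosomal protein genes, 14 were lower and 2 higher, with 15 and 2 adjusted over the list alone (median -0.06, camera adjusted p = 0.0117; adjusted p = 0.375 with an estimated correlation).

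Among mitochondrial genes, 28 of 74 ribosomal protein genes were higher and 6 lower in the CA2 dendritic layer. Adjusted over the list alone these were 30 and 7, with Mrpl42 at 0.84 and Mrpl15 at 0.57. The list median was 0.22 (camera adjusted p = 1.03e-06, and adjusted p = 0.215 with an estimated correlation). Of 22 dynamics and calcium uptake genes, 11 were higher and 2 lower by both counts (median 0.39, camera adjusted p = 1.01e-05; adjusted p = 0.175 with an estimated correlation), with the fusion protein Mfn1 at 0.72, Ppargc1a at 0.65 and the mitochondrial transcription factor Tfam at 0.65. Of 33 complex I genes, 11 were higher and 3 lower, with 12 and 4 adjusted over the list alone (median 0.24, camera adjusted p = 3.43e-04; adjusted p = 0.25 with an estimated correlation), with Ndufs1 at 0.81 and Ndufa9 at 0.72. Of 25 genes of complexes II to IV, 9 were higher and 1 lower, with 9 and 2 adjusted over the list alone (median 0.22, camera adjusted p = 1.57e-04; adjusted p = 0.215 with an estimated correlation), with cytochrome c (Cycs) at 0.92. Of 18 TCA cycle enzymes, 6 were higher, with 7 adjusted over the list alone (median 0.25, camera adjusted p = 3.35e-05; adjusted p = 0.207 with an estimated correlation), with Dld at 0.78 and Sucla2 at 0.60. Of 15 ATP synthase genes, 2 were higher and 1 lower (median 0.21, camera adjusted p = 0.0239; adjusted p = 0.303 with an estimated correlation), and the 6 measured transcripts encoded in mitochondria did not pass (camera adjusted p = 0.936). As deposited, the medians of the 6 lists that passed, in the order given, were 0.11, 0.28, 0.13, 0.11, 0.14 and 0.10, and after quantile normalization 0.13, 0.25, 0.09, 0.09, 0.10 and 0.03. After it the lists of complex I (adjusted p = 0.138), ATP synthase (0.386), interneurons (0.104), astrocytes (0.189) and CA2 markers (0.0686) did not pass. In the interaction, the lists of dynamics, TCA cycle, complexes II to IV and ATP synthase did not pass (camera adjusted p = 0.282, 0.492, 0.0896 and 0.282). The dynamics and TCA cycle lists were also higher in CA2 cell bodies (camera adjusted p = 0.00103 and 4.11e-04). For these lists, a difference particular to the dendritic layer was thus not shown. The 6 mitochondrial lists that passed as deposited averaged 8.27 to 10.49 on the CA2 dendrite arrays. Of the 6025 brightest genes, with mean levels from 8.14, 1822 were called higher and 1184 lower in CA2. Rises were thus common among bright genes, but in each of the 6 lists they outnumbered falls by more than among these genes. For ATP synthase this rests on 2 genes against 1. At mean levels from 7.01 to 8.14, just below the average of the mitochondrial ribosomal list, 1040 genes were higher and 1037 lower. Level alone therefore does not match the balance of rises and falls in these lists. Other lists of like level were not drawn, so whether the excess is particular to mitochondrial genes was not tested.

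Of 16 oligodendrocyte markers, 11 were higher, with 12 adjusted over the list alone (median 0.68, camera adjusted p = 8.47e-10; adjusted p = 0.18 with an estimated correlation), with Tspan2 at 1.27. Of 17 endothelial markers, 11 were higher, with 11 higher and 1 lower adjusted over the list alone (median 0.59, camera adjusted p = 1.03e-06; adjusted p = 0.112 with an estimated correlation), with Abcb1a at 0.71, and of 12 mural markers 5 were higher, with Acta2 at 1.36 (median 0.25, camera adjusted p = 0.00248; adjusted p = 0.303 with an estimated correlation). Of 19 microglia markers, 15 were lower and 1 higher by both counts (median -0.34, camera adjusted p = 4.65e-04; adjusted p = 0.175 with an estimated correlation), with P2ry12 at -0.70 and Cx3cr1 at -0.58. The 1 that was higher, the protease Ctss (0.49), was named after its value was seen. Of 20 interneuron markers, 7 were higher and 4 lower by both counts (median 0.16, camera adjusted p = 0.00846; adjusted p = 0.371 with an estimated correlation), with Reln at 1.39 and Pvalb at 0.80. Of 19 astrocyte markers, 4 were higher and 1 lower (median 0.18, camera adjusted p = 0.0117; adjusted p = 0.289 with an estimated correlation).

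Between the dendritic layers 9105 genes were called, 3487 higher and 5618 lower in CA2, of which 88 and 107 were at least 2-fold. A fit of these 2 groups alone called 3109 genes, 1623 higher and 1486 lower. Both groups varied more than the cell body layers, which share the spread estimate of the main fit. Rises made up 38.3% of the 9105 genes called as deposited. The share was 56.4% after quantile normalization and 70.3% after median centring. As deposited, rises made up 50.7% of the called genes above the median level against 5.7% of those at or below it. Without the 3 arrays with oocyte transcripts the share was 53.5%. Of the 29 lists, 19 passed with the preset correlation and 0 with an estimated one, where 6 had an unadjusted p under 0.05, and fry called 19. Without the 3 arrays with oocyte transcripts 1918 genes were called, and Pcp4 (adjusted p = 0.325), Camk2a, Avpr1b, P2ry12, Arc, Ctss and Pvalb did not pass, nor did the CA2 marker, astrocyte, mural and cytosolic ribosomal lists. The Pcp4 call was also lost without replicate 2 (adjusted p = 0.139), CA1 dendrite 1 (0.0778) or 2 (0.0594) or CA2 dendrite 2 (0.0746) and with array weights (0.0646), and that of Ddn without replicate 1 (adjusted p = 0.0588) or 2 (0.0604).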

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

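The tests of weak target, of glial and vascular cells, of captured CA2 tissue, of shared cells, of exchanged labels and of a single mouse in this part were chosen only after the results they weigh were seen; those of an array-wide lift, of oocyte RNA and of other splits of the arrays were written before their values were seen.

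All results in this and the next 2 paragraphs stand here because the layer difference of CA2 differed from that of CA1 by the test of the interaction, and values are the CA2 minus the CA1 difference (log2). This held for 3504 genes. Among genes of pyramidal neurons and those with the largest values, it was lower for Cpne4 (-3.43), Cacng5 (-3.12), Pcp4 (-2.97), Sostdc1 (-2.84), Mctp1 (-2.81), Fstl5 (-2.79), Nrip3 (-2.63), St8sia6 (-2.56), Amigo2 (-2.53), Map3k15 (-2.42), Necab2 (-1.76), Rgs14 (-1.11) and Neurod6 (-0.61). It was higher for Man1a (2.71), C1ql3 (2.59), Calb1 (2.51), Adgrl2 (2.42), Ndst4 (2.05), Kcnh7 (1.93), Ccn3 (1.75), Wfs1 (0.99), Epha7 (0.64) and Fibcd1 (0.57). Many of these genes differed in level between the cell body layers, and such values largely restate the region. Cpne4 read 6.27 in CA1 and 11.27 in CA2 cell bodies, and Mctp1 5.95 and 9.94.

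Genes of glia, vessels and interneurons gave 1.16 for Ndnf, -1.32 for Aldh1a1, -0.61 for P2ry13, -0.42 for Cx3cr1, -0.82 for C1qa, -0.68 for Itgam, -0.54 for Fcrls, -0.41 for Trem2, 1.30 for Acta2, 0.33 for Abcb1a, 0.95 for Reln, 0.52 for Gad1, -1.33 for Sst and -0.53 for Cck. Matrix genes gave -1.67 for Acan, -1.56 for Vcan, -1.48 for Hapln4 and 0.56 for Hapln1. Genes of synapses, dendrites and channels gave -0.57 for Ppp1r9b, -0.92 for Psd, -0.88 for Agap2, -0.66 for Cplx2, -0.71 for Dlgap3, -0.67 for Camkv, -0.43 for Eef2, 0.42 for Gria2, 0.72 for Grik1, 0.97 for Grm3, -0.75 for Ncs1, 1.59 for Necab1, -1.65 for Kcnv1, -2.18 for Slc9a4 and -1.75 for Ptgs2. Somatic, mitochondrial and nuclear transcripts gave -1.29 for Rprml, -0.71 for Stmn2, -0.84 for Slc17a7, -0.65 for Uchl1, 0.66 for Mrps9, 0.64 for Mrpl11, 0.44 for Ndufv2, 0.35 for Ndufa7, -0.99 for Mcu, 0.44 for Malat1 and 0.74 for Kcnq1ot1.

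Of the gene lists, the median differences were -1.32 for CA2 markers, 0.91 for CA1 markers, -0.47 for CA3 markers, -0.51 for somatic transcripts, -0.37 for dendritic mRNAs, -0.46 for microglia, 0.19 for interneurons, 0.13 for complex I, 0.013 for mitochondrial ribosomal proteins and 0.31 for nuclear-retained RNAs. The median over all genes was -0.11, from -0.17 among the dimmest 20% to 0.05 among the brightest 20%. Of all genes 11.6% were called, against 2 of 33 complex I and 3 of 74 mitochondrial ribosomal protein genes. These 2 lists passed against that background and not through many called members. The CA2 marker list alone also passed with an estimated correlation. Its members averaged 7.13 in the CA1 and 8.84 in the CA2 cell body layer, so its value largely restates the region. A like limit holds for the CA1 markers (9.07 and 7.46) and the CA3 markers (6.93 and 8.19).

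Pcp4, a gene of CA2 neurons, rose by 2.21 from the CA1 cell body to the CA1 dendritic layer (1.91 to 2.60 over the alternatives, adjusted p from 1.4e-06 to 0.0016). If CA2 tissue had been captured with the CA1 dendritic layer, CA2 markers should rise there. Of the 18 markers fixed in advance 8 rose and 5 fell (median 0.12), with Rgs14 at -0.88 and Amigo2 at 0.13. The 18 include Pcp4 itself, which had the largest rise of the list, and Vcan, which is also a precursor marker. Even with these the markers did not pass against all other genes (camera adjusted p = 0.909). Tested alone they did (fry adjusted p = 0.00179), but fry called 25 of the 29 lists in CA1, so that pass says little. As the members went both ways and the list holds the gene to be explained, it cannot decide this, which was left open. Cells that both dendritic layers share were left open as well: over 46 other genes at least 2-fold higher in both CA2 layers than in CA1 cell bodies and, like Pcp4, not higher in CA2 dendrites than in CA2 cell bodies, the CA2 dendritic layer stood 0.50 above the CA1 dendritic layer. A shift shared by genes near its level does not account for the rise of Pcp4, as 99.8% of these 461 genes changed less. Pcp4 read at least 8.63 on every array, against a median level of features of 5.76. The test therefore says nothing about a lift of dim features.

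Called genes in CA1 were more often higher than lower in the dendritic layer (60.5%, and 52.6% to 62.5% over the alternatives). If weaker labelled target on the CA1 dendrite arrays had lifted dim features, the excess should lie at low levels, and rises made up 91.0% of the called genes at or below the median level, 52.0% above it and 36.7% among the brightest 20% of genes. At or below it the median change of genes was 0.16, and control features without mouse sequence rose by 0.11, so a technical part of the low-level rises is likely. The share was 56.5% after quantile normalization and 52.9% after median centring, so how much of the excess is technical was not settled. Glial and vascular cells, the biological explanation, stayed open, as the share in CA2, where their markers also rose, was 47.7% but ran from 42.5% after scaling to 56.0% with a 2-fold minimum.

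Oocyte transcripts stood out on CA2 cell body 1 and CA2 dendrite 2 and 3. Of 27 measured oocyte markers held out from the finding, 25 (92.6%) were higher on all 3 arrays than on the other 3 CA2 arrays, against 2.4% of all genes, with a median difference of 1.39. An exchange of the CA2 cell body 1 and CA2 dendrite 1 labels was excluded, since CA2 cell body 1 differed from CA2 dendrite 1 by 3.08 in Neurod6 and by -3.22 in Gfap. Tissue of 1 mouse was excluded as far as the number stands for the mouse, as the 3 arrays carry 3 replicate numbers. Oocyte RNA in those 3 libraries fits these values. The labels describe all 3 mice as male, so by the labels it did not come from oocytes of these mice. Where it entered was not tested, and the labels give no group on which another biological explanation could be tested.

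With 3 arrays against 3 there are 10 splits, so the share of splits with as many calls as the real one cannot fall under 0.1. In each of the 5 comparisons 1 split, the real one, reached its count (14122, 10251, 3504, 6367 and 9105 genes), and any other split called at most 108 genes between the CA2 layers and 0 in the other comparisons by limma, so this cannot settle whether a count arose by chance.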

How the results depend on the processing

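The fit without the 3 CA2 arrays with oocyte transcripts and the fit with array weights were added only after the data were seen. Of the named genes under the alternatives that left out no single array or number, 2627 values kept side and direction, 124 were no longer called, 26 became called and 0 reversed; for lists these numbers were 726, 111, 32 and 1. The reversed value was the matrix list in the interaction, at -0.06 with fry (directional adjusted p = 0.0013), where camera gave the opposite direction and no call. With a 2-fold minimum, which removes small differences by construction, 1849, 1764, 414, 625 and 195 genes were left in CA1, in CA2, in the interaction, between cell bodies and between dendrites. Every feature in place of every gene gave 22235, 15383 and 11487 in CA1, in CA2 and between cell bodies, out of more tested features, and moved the higher share from 47.7% to 55.3% in CA2, from 41.4% to 61.5% in the interaction and from 50.3% to 33.3% between cell bodies; the cause of these moves was not tested. Between dendrites, the 2 groups alone gave 3109 genes and array weights 5579, against 9105 in the main fit. The main fit shares 1 estimate of spread over the 4 groups. The median SD of a gene was 0.129 and 0.0929 in the CA1 and CA2 dendritic layers, against 0.0751 and 0.0721 in the cell body layers. Between cell bodies the 2 groups alone gave 7594 genes, more than the 6367 of the main fit. The main fit thus tests the dendritic layers with a smaller spread than their own, and 9105 is likely too high. In CA1 the 2 groups alone gave 11673 genes against 14122 in the main fit, so that count may be too high as well. Without the 3 CA2 arrays with oocyte transcripts, so with fewer samples and a lone CA2 dendrite array assumed to vary like the others, counts were 5707 in CA2, 699 in the interaction, 1918 between dendrites and 4473 for the overlap of the layers. With an estimated correlation camera called 4, 8, 1, 2 and 0 of 29 lists, where the estimates reached 0.86 against the preset 0.01. Fry without direction called 29 in CA2, 27 in the interaction and 27 between cell bodies. Camera weighs a list against all other genes, while fry tests its members alone. With 34.0%, 11.6% and 21.1% of all genes called in these 3 comparisons, most lists can pass fry, and the 2 tests answer different questions. Without the replicate block the counts were 14757, 10625, 4387, 6864 and 10138. That changed calls of the immediate early gene list in CA1 (adjusted p = 0.0563), Fibcd1 in CA2 (0.0359), Map2 in the interaction (0.0277), Gfap between cell bodies (0.0788), Amigo2 between dendrites (0.0415) and the mitochondrial ribosomal list between cell bodies (0.0479), and no other call of named genes or lists.

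Leaving out 1 replicate number or 1 array gave 9706 to 14706 genes in CA1, 7986 to 9236 in CA2, 697 to 4878 in the interaction, 3451 to 4890 between cell bodies and 3663 to 9706 between dendrites, with fewer samples in each fit; where a number is left out each group keeps 2 arrays. Of the named genes 2693 values kept their side, 137 were no longer called and 11 became called, and of lists 412, 15 and 8. Lists called were 21 to 23, 19 to 20, 10 to 12, 12 to 15 and 16 to 17. The interaction count moved by over 1.5 times without any 1 replicate number, any 1 CA1 cell body array, CA2 cell body 2 or 3, or CA2 dendrite 1 or 2. The cell body count did so without any 1 replicate number, and the dendrite count without replicate 1 or 2 or CA2 dendrite 2. The median level of features was 5.76, near the level of the control features without mouse sequence (5.23 to 5.34), so absence of a call among dim genes says little.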

Other observations

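The regional differences of the cell body and dendritic layers were set side by side. Of the 30142 genes, 1522 were higher and 1178 lower in CA2 in both layers, where independent lists would share 370.8 and 589.3, and 286 were called in opposite directions. The differences correlated at r = 0.465 (Pearson) and rho = 0.412 (Spearman) across genes, which are not independent replicates, and region and run cannot be told apart in either layer. Cpne4, known from CA2 and CA3 neurons, was 5.01 higher between cell bodies and 1.57 higher between dendrites, and Map3k15 3.08 and 0.66 higher. Wfs1, a CA1 gene, differed by -2.72 and -1.73 and Mpped1 by -1.32 and -1.46. The activity-induced genes Arc (-1.14 and -1.39), Egr3 (-0.93 and -1.27) and Homer1 (-0.65 and -0.82) were lower in both layers.

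Receptor and channel genes differed one by one between the regions although their lists did not pass. Between cell bodies, 2 of 14 ionotropic glutamate receptor genes were higher and 5 lower in CA2 (camera adjusted p = 0.232), with the NMDA receptor subunit Grin2a at -0.82 and the AMPA receptor subunit Gria1 at -0.36. Between dendrites 4 were higher and 7 lower (camera adjusted p = 0.663), with the kainate receptor subunit Grik5 at -0.96. Of 22 potassium and HCN channel genes, 7 were higher and 7 lower between cell bodies (camera adjusted p = 0.527), and 4 higher and 9 lower between dendrites (camera adjusted p = 0.731). Kcnq5 (1.39) and Kcnh1 (1.27) were higher in CA2 cell bodies, and Kcnq3, a channel of the M current, was lower in both layers (-1.10 and -0.79). The Gria1 call between cell bodies was lost without replicate 2.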
